A study of Rattus norvegicus with 9 samples.

How the data were processed

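RNA was sequenced from rat brain in 9 libraries: 3 from sham-operated rats (sham 1, 3 and 5), 3 from rats with an occluded middle cerebral artery (model 1, 3 and 4) and 3 from rats with the same occlusion that had received astaxanthin (astaxanthin 1, 2 and 3), per the labels. Library numbers are those of the labels. The labels do not say that a library stands for a separate animal or that an equal number marks a shared day, so the p-values given here measure only the spread between samples. The deposited tables held values for 22888 genes and 45893 transcripts, with a chromosome, start and end for each. Per the submitters' processing notes, FastQC, STAR, StringTie and DESeq2 and the genome build rn7 were used; no version or setting was stated, and coordinates are given as the tables hold them. In both tables the values the authors deposited were signal values already normalized by library. Every value was a whole multiple of a single value per library within a tolerance of 0.01, in 100% of the entries, so whole reads could be recovered by dividing by it. The factors by which the authors had divided the reads lay below the median-of-ratios size factors of the recovered reads, which were 1.02 to 1.03 times as large; how the deposited factors were set was not stated. Gene values equalled the sum of their transcripts in all 22888 genes. The labels do not say whether counting used the strand, so reads of overlapping antisense genes cannot be told apart, and reads of near-identical copies (the kininogens Kng1 and Kng2l1, or neighbouring chemokines) may be divided between them.

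Recovered totals ranged from 52268061 to 76311125 reads per library. A count of 0 in a library allows up to 3 reads, which corresponds to 2.87 to 3.52 normalized reads depending on the group, and a fold change against a group with 0 reads in every library was computed from the mean of the other group against that floor, taken per library. A group mean under the floor that was not 0 in every library (Msr1, Esm1 and C6 in sham) leaves the size of the fold change to the pseudocount. Floors cover counting error only, while standard errors measure the spread between libraries. Of the gene symbols, 16856 matched a RefSeq symbol of the GRCr8 assembly and 1503 matched a synonym only; that assembly was used for names and not for positions. The genome sequence was not used here.

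The comparisons were model against sham, astaxanthin against model and astaxanthin against sham. The test, the groups, the gene lists and the rule for named genes were fixed before the data were examined. The first choice of test was edgeR on raw counts, with limma as the stated fallback if the table held other values; since the deposited values were normalized, limma 3.58.1 (R 4.3.3) was used on log2(value + 1), with trend and robust moderation, all 9 libraries in 1 fit and group as the only term. Genes with a value of at least 0.5 in at least 3 libraries were tested, 17770 in all, two-sided, with the Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Fold changes are differences of mean log2(value + 1) with their standard errors (SE); levels are means of normalized reads with standard deviations (SD) over 3 libraries. With 3 libraries against 3, groups that do not overlap arise by chance in 10% of genes on average. Since genes vary together, the share in a single grouping can lie away from that, and it was not computed for other groupings. An exact permutation test of a single gene could not go below a two-sided p of 0.1, so no such test is given.

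Altogether 31 gene lists (pathways, cell type markers and measures of RNA quality) were tested per comparison with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the lists. Beside it stand camera with the correlation estimated from the data, fry of limma, and the number of members past the threshold over all genes tested and adjusted over the list alone. No list passed with an estimated correlation in any comparison. Named genes were, per comparison, the 8 largest rises and 8 largest falls among genes past the threshold whose groups did not overlap, or the 4 with the smallest p in a direction where none passed; up to 4 members with the smallest p of each list described; and, whatever their values, a set that included Tlr2, Tlr4, Myd88, Nfkb1, Rela, Bax, Bcl2, Il1b, Il6, Tnf, Hmox1, Gfap and Aif1. Genes named outside this rule are said to have been chosen after their values were seen.

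The script was tested on simulated data with 100 genes changed by 2-fold and 100 by 8-fold. For model against sham (17662 genes), 3% of the 2-fold and 81% of the 8-fold changes were recovered, with 2 false calls. For astaxanthin against model (17670 genes) the shares were 4% and 87%, with 8 false calls, and for astaxanthin against sham (17653 genes) 8% and 82%, with 10 false calls. Changes near 2-fold were therefore mostly out of reach. In the simulated lists, drawn with noise uncorrelated between genes, a shifted list was found and 0 of 20 unshifted lists were called. Members of the real lists had estimated correlations from 0.1 (cell cycle) to 0.86 (ribosomal proteins). The simulation therefore does not show how often camera calls unshifted lists of correlated genes.

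Because comparisons share libraries, the correlation of fold changes and the covariance were set beside 100 simulations of unchanged groups sharing those libraries. The share of genes with opposite signs and the median return were set beside 100 simulations without a treatment effect. These kept the differences of model from sham, shrunk by a factor of 0.69 for their noise, and gave astaxanthin the model mean. In each, the 848 genes with the smallest p between model and sham were taken. Both kinds were run once with noise pooled over all groups and once with noise by group. Noise by group here means sham apart from model and astaxanthin, which were pooled with each other. The spread of model 3 and of astaxanthin 1 therefore entered both of those groups, and noise of each group alone was not simulated. Position between sham and model was computed per library on the log2 scale, with 0% at the sham mean and 100% at the model mean. The alternatives tried were DESeq2 1.42.0 and edgeR 4.0.16 on the recovered reads, other size factors, other filters, a pseudocount of 0.1 and stricter thresholds. Fits of only the compared libraries, a replicate block, array weights, fry, and fits without each library in turn were also tried. Array weights and the fits without astaxanthin 1 and model 3 together were added after seeing the data. So was the run of edgeR, the first choice of test for raw counts, on the recovered reads. The transcript table entered no comparison between groups in the results and is treated among the additional observations.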

Results

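Transcript levels were measured by RNA sequencing in brain tissue of male Sprague-Dawley rats whose middle cerebral artery had been occluded on a single side, a model of ischemic stroke. The 9 libraries formed 3 groups of 3. Sham-operated rats served as the uninjured reference. The model group had the occlusion alone. The astaxanthin group had the occlusion after 7 days of gavage with astaxanthin, a carotenoid antioxidant, at 45 mg/kg, which the labels call the medium dose. Tissue was collected 1 day after the occlusion, and the labels name the brain without a region or side. The study asked about apoptosis of nerve cells and Toll-like receptor signalling, so genes of both were followed in every comparison. Recovered reads came to 52268061, 54916035 and 62148215 in sham 1, 3 and 5, to 66637824, 60640476 and 70725032 in model 1, 3 and 4, and to 57205011, 63498267 and 76311125 in astaxanthin 1, 2 and 3. Mitochondrial transcripts took 6.46% to 10.4% of them.

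The libraries differed in ways that the groups did not name. The first principal component held 30.4% of the variance and placed the sham libraries between -93.5 and -73.9, the model libraries between 33.1 and 120.6, and the astaxanthin libraries between -1.66 and 23.3. Astaxanthin 1 stood apart on the second component (19.8% of the variance), at -148.5 against -17.0 to 47.4 elsewhere. It carried genes of cerebellar neurons. All 17 cerebellar markers examined, a set chosen after the values were seen, were highest in it, and 10 of them were at least 10-fold above the next library. Gabra6, a receptor subunit of cerebellar granule cells, stood at 44128 normalized reads in astaxanthin 1 and at 255.9 or less in the other libraries. Of 19 choroid plexus and ependymal genes, 14 were highest in astaxanthin 1 and 3 in sham 5, while Ttr, the transthyretin made by choroid plexus, reached 178856 normalized reads in astaxanthin 1 and 108678 in sham 5 against 14199 or less elsewhere. Model 3 had the highest Mbp, a myelin protein gene (1076966 normalized reads against 503330.3 or less), though its oligodendrocyte and myelin list lay at -0.03 from the sham mean, below 0.19 in sham 1 and 0.43 in sham 5. It also had the highest S100a9, a neutrophil gene (8232 against 433.1 or less). Its pan-neuronal genes lay on average at -1.75 log2 units from the sham mean, against -0.49 in model 1 and -0.34 in model 4. Ttr, Mbp and S100a9 were named here for their levels in single libraries, after their values were seen.

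**Figure D1:**
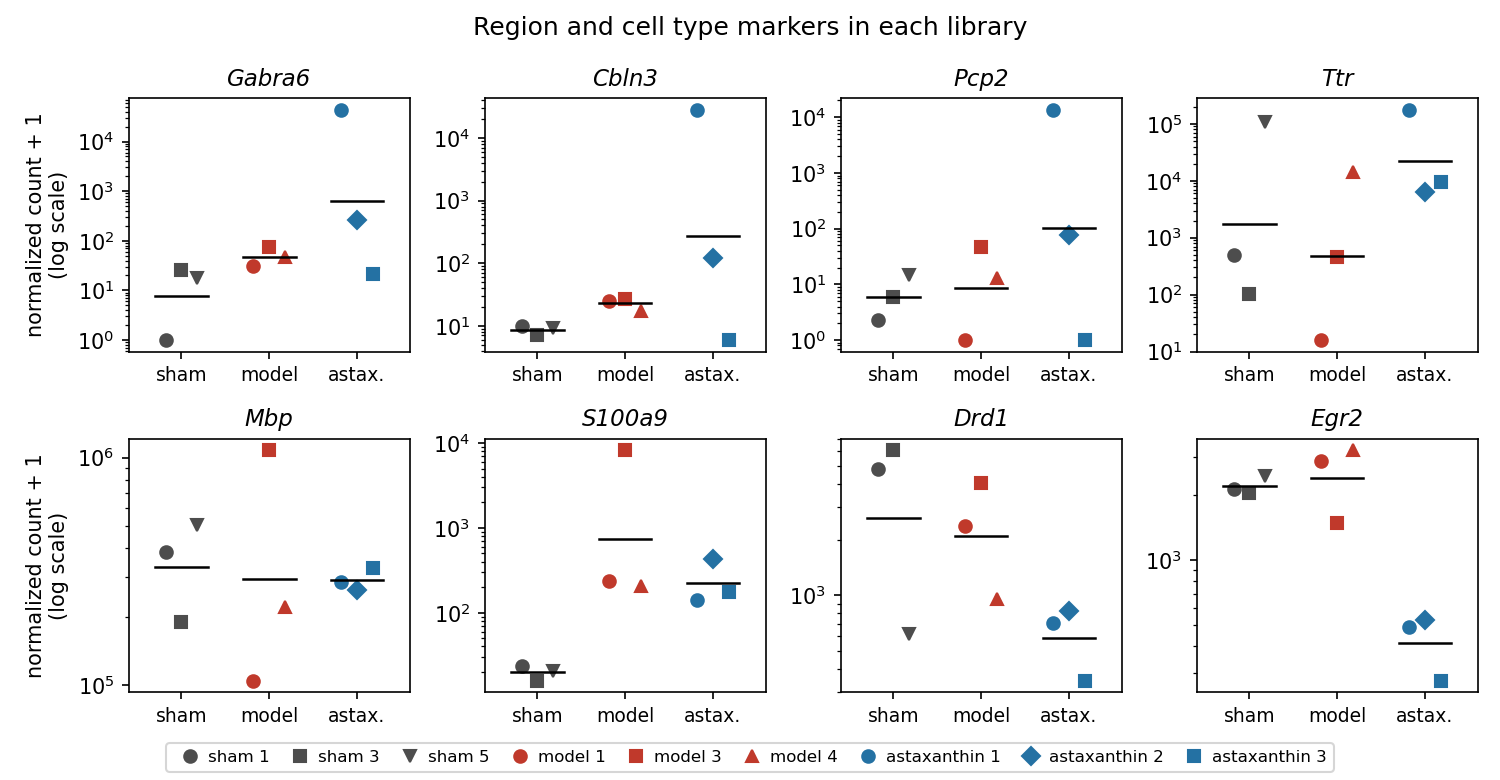
Normalized count plus 1 (log scale) of 8 region and cell type markers in each library, grouped as sham, model and astaxanthin (astax.), with a bar at the geometric mean of each group and a marker shape for each library number. Gabra6, Cbln3 and Pcp2 were highest in astaxanthin 1, Ttr was highest in astaxanthin 1 and sham 5, and Mbp and S100a9 were highest in model 3.

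The comparison of model with sham asked what the occlusion alone did 1 day later. Chemokine, cytokine, kininogen and scavenger receptor genes were far higher in the model libraries. Ccl2 (chromosome 10, 67005424 to 67007226), a chemokine that attracts monocytes, had 0 reads in all 3 sham libraries and 8198 ± 2026 normalized reads (SD, n = 3) in the model libraries, at least 2330-fold higher (limma adjusted p = 0.000627). Its neighbour Ccl7 (chromosome 10, 67016446 to 67018303) went from 0 to 2401 ± 277 (SD, n = 3; limma adjusted p = 0.000785). Il11, a cytokine of the interleukin-6 family, and the kininogen genes Kng1 and Kng2l1 were at 0 in sham and at least 380-fold, 449-fold and 736-fold higher in model, each with a limma adjusted p of 0.000785. Ccl20 was at least 391-fold higher by its mean, Lbp, the binding protein for bacterial lipopolysaccharide, had a log2 fold change of 9.29 ± 1.44 (SE), and Msr1, a macrophage scavenger receptor, one of 9.21 ± 0.99 (SE), or 11.48 with a pseudocount of 0.1, since its sham mean of 2.416 lay under the floor of 3.52. The means of Kng1, Kng2l1, Ccl20 and Lbp rested largely on model 3. They stood at 3349.7, 5825.6, 3554.5 and 28010.7 normalized reads in it, and at no more than 798.8, 1028.8, 338.9 and 2226.1 in model 1 and 4. Among the largest falls were Ltc4s (log2 fold change -4.35), Btbd17 (-3.20), Ngb, the neuronal oxygen-binding protein neuroglobin (-2.94), Vwa5b1 (-2.57), Tril (-2.52), Abcd2 (-2.48) and Mcf2 (-2.45), with limma adjusted p between 0.0122 and 0.0472. None of these falls kept its call in each of the 9 fits without 1 library. Btbd17 kept it in 1, Tril in 2, Ltc4s, Abcd2 and Mcf2 in 3, Vwa5b1 in 5 and Ngb in 8.

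Altogether 848 of 17770 genes passed the threshold in limma, 613 higher and 235 lower in model, and 717 of them differed at least 2-fold. The groups did not overlap in 35.6% of all genes, against 10% by chance. The count depended on single libraries. It was 72 without sham 3, 79 without sham 1, 171 without sham 5, 124 without model 1, 549 without model 3, 493 without astaxanthin 2, 565 without astaxanthin 3 and 1608 without astaxanthin 1. DESeq2 on the recovered reads called 2943 genes, and edgeR, the first choice of test for raw counts, called 761. Without astaxanthin 1 and model 3 together, a setting chosen after seeing the data, limma called 2710. Of the 67 genes past the threshold that are named for this comparison, 26 kept their call in each of the 9 fits without 1 library, among them Ccl2, Ccl7, Il11, Kng1, Kng2l1, Msr1, Cd14, Tlr1, Il1b, Tnf and Hmox1. Of the named genes that fell, only Otof kept its call in each of these fits. Without sham 1 the fewest of the 67, 27, kept their call.

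Toll-like receptor signalling genes were higher in model as a list. Of 41 measured, 9 rose and 1 fell over all genes tested, and 14 passed when adjusted over the list alone. The median log2 fold change was 0.77 (camera adjusted p = 7.94e-06, and adjusted p = 0.301 with an estimated correlation). The strongest call was Cd14 (chromosome 18, 28335340 to 28337261), a co-receptor for lipopolysaccharide, from 44.1 ± 25.8 to 3855 ± 1583 normalized reads (SD, n = 3; log2 fold change 6.51 ± 0.61 SE, limma adjusted p = 0.00329). Tlr1 went from 28.6 ± 11.96 to 477 ± 40.2 (limma adjusted p = 0.00365), and the kinase Map2k3 had a log2 fold change of 1.84 ± 0.22 (SE). Myd88, the adaptor shared by most Toll-like receptors, rose from 384 ± 23.8 to 2308 ± 583 (SD, n = 3; limma adjusted p = 0.0140). Its call was kept in 5 of the 9 fits without 1 library, with a limma adjusted p of 0.0724 without sham 1. Tlr2 and Tlr4 did not pass, with log2 fold changes of 1.46 ± 0.51 (SE; limma adjusted p = 0.133) and 1.49 ± 0.54 (SE; limma adjusted p = 0.145). The transcription factor subunits Nfkb1 (0.94, limma adjusted p = 0.0791) and Rela (1.14, limma adjusted p = 0.0647) did not pass either. These calls depended on the tool. DESeq2 on the recovered reads called Tlr2, Tlr4, Nfkb1 and Rela higher, with DESeq2 adjusted p of 0.0249, 0.0263, 0.00937 and 0.00398. The member that fell was the kinase Map2k6 (-1.96), chosen after its values were seen. Of 21 inhibitors and feedback targets of NF-kappaB, 6 rose and 1 fell over all genes and 14 passed when adjusted over the list alone, with a median of 1.5 (camera adjusted p = 1.80e-06, and adjusted p = 0.301 with an estimated correlation). Socs3, a feedback inhibitor of cytokine signalling, had a log2 fold change of 6.19 ± 0.65 (SE), Nfkbiz one of 2.83 ± 0.35 (SE) and Icam1, a leukocyte adhesion molecule, one of 3.81 ± 0.67 (SE).

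Apoptosis genes were also higher in model. Of 40 measured, 7 rose and 0 fell over all genes, 15 passed when adjusted over the list alone, and the median log2 fold change was 0.57 (camera adjusted p = 7.21e-05, and adjusted p = 0.301 with an estimated correlation). The tumour necrosis factor receptor Tnfrsf1a (2.92 ± 0.41 SE) and the kinase Ripk1 (1.31 ± 0.20 SE) rose. The pro-apoptotic Bax and the anti-apoptotic Bcl2 did not pass, with log2 fold changes of 0.40 ± 0.23 (SE; limma adjusted p = 0.319) and -0.17 ± 0.26 (SE; limma adjusted p = 0.722). Of 24 genes of the inflammasome, pyroptosis, necroptosis and ferroptosis, 7 rose over all genes and 7 passed when adjusted over the list alone, with a median of 1.14 (camera adjusted p = 4.42e-07, and adjusted p = 0.3 with an estimated correlation). They included Il1b, at 0 in sham and at 438.6 ± 403.5 normalized reads in model (SD, n = 3; at least 125-fold higher by the mean), and Ripk3 (4.58 ± 0.73 SE), a kinase of necroptosis.

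**Figure D2:**
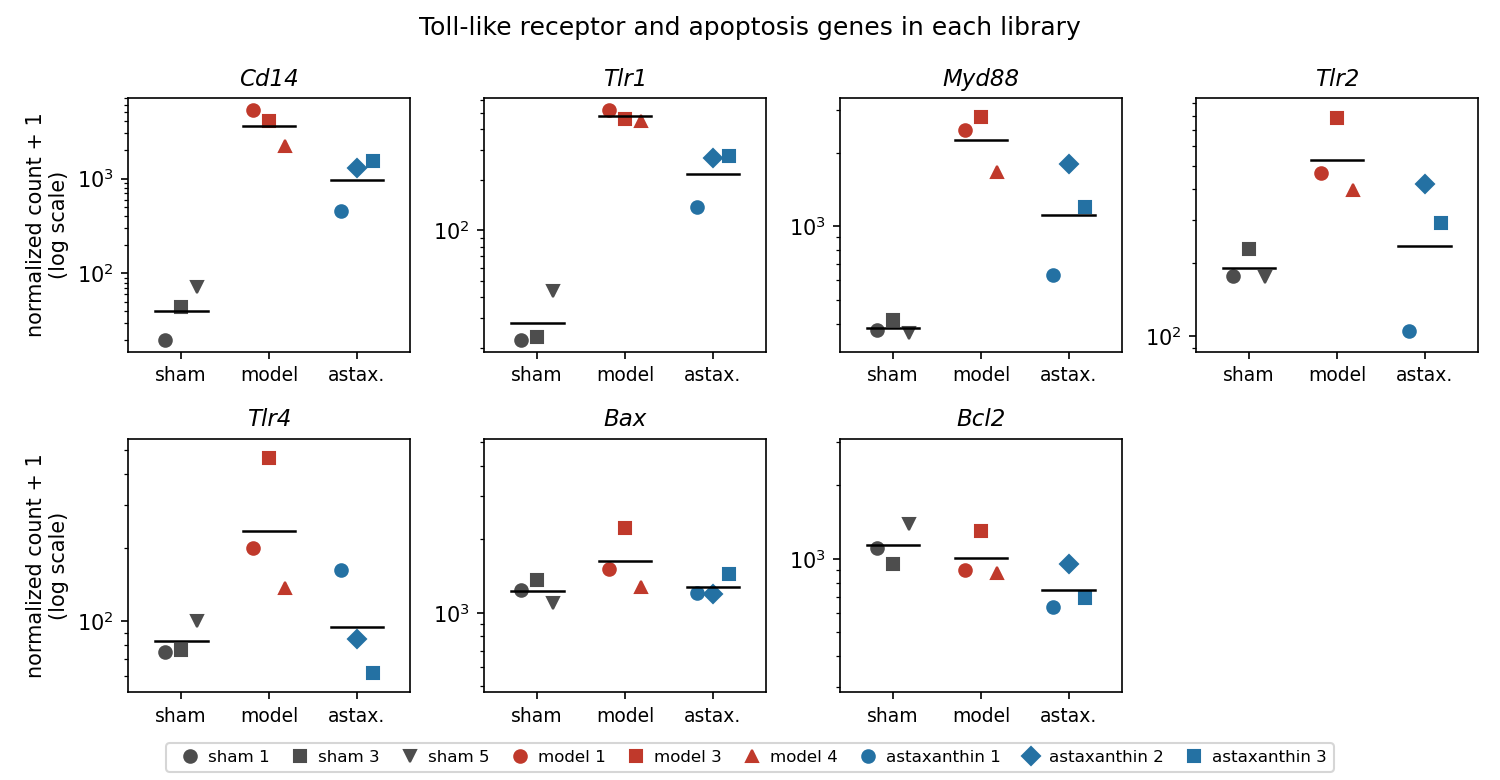
Normalized count plus 1 (log scale) of 5 Toll-like receptor genes and 2 apoptosis genes in each library, grouped as sham, model and astaxanthin (astax.), with a bar at the geometric mean of each group and a marker shape for each library number. In limma, Cd14, Tlr1 and Myd88 rose between sham and model, Tlr2, Tlr4, Bax and Bcl2 did not pass, and no gene passed between model and astaxanthin.

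The largest list-wide rises were in inflammation, matrix remodelling and astrocyte reactivity. Of 36 cytokine and chemokine genes, 21 rose over all genes and 25 passed when adjusted over the list alone, with a median log2 fold change of 4.89, or 4.53 with the 10 members at 0 in sham set to their bound. Il6 had a log2 fold change of 8.17 ± 1.16 (SE), Lif one of 7.87 ± 0.70 (SE), and Tnf, at 0 in sham, was at least 31.3-fold higher. Matrix remodelling (18 of 27 rose, 24 adjusted over the list alone, median 3.23) included Timp1 (7.74 ± 0.82 SE), Plau (5.74 ± 0.59 SE) and Plaur (4.96 ± 0.53 SE). Reactive astrocyte markers (18 of 24 rose, 23 adjusted over the list alone, median 4.19, or 4.16 with 1 member at its bound) included Ptx3 (6.85 ± 0.60 SE), Stat3 (2.21 ± 0.22 SE) and the intermediate filament gene Gfap. Gfap rose by 2.79 ± 0.62 (SE; limma adjusted p = 0.0420) and kept that call in 1 of the 9 fits without 1 library, with a limma adjusted p of 0.148 without sham 3. Camera gave adjusted p of 7.78e-20, 1.06e-19 and 2.07e-18 for the 3 lists, each with an adjusted p = 0.209 with an estimated correlation. Complement genes (6 of 21 rose, 13 adjusted over the list alone, median 1.61, camera adjusted p = 2.21e-08, and adjusted p = 0.301 with an estimated correlation) included Itgax (7.35 ± 0.78 SE) and C6 (6.92 ± 1.22 SE, or 9.17 with a pseudocount of 0.1).

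Heat shock, immediate early, hypoxia and cell cycle lists moved the same way. Heat shock and unfolded protein genes rose (5 of 25 over all genes, 14 adjusted over the list alone, median 0.89, camera adjusted p = 6.79e-09, and adjusted p = 0.301 with an estimated correlation). Hmox1, the inducible heme oxygenase, went from 289 ± 50.9 to 23848 ± 19348 normalized reads (SD, n = 3; limma adjusted p = 0.00595). The small heat shock protein gene Hspb1 had a log2 fold change of 6.02 ± 0.73 (SE). Immediate early genes, which neurons switch on with activity or stress, rose (10 of 30 over all genes, 12 adjusted over the list alone, median 1.11, camera adjusted p = 4.01e-07, and adjusted p = 0.3 with an estimated correlation). They were led by Inhba (5.08 ± 0.56 SE) and Maff (4.40 ± 0.61 SE). Hypoxia and glycolysis genes rose (6 of 25, 9 adjusted over the list alone, median 0.47, camera adjusted p = 0.000989, and adjusted p = 0.354 with an estimated correlation), among them Hif1a (1.45 ± 0.20 SE). Cell cycle genes rose (4 of 24, 8 adjusted over the list alone, median 0.78, camera adjusted p = 0.000272, and adjusted p = 0.301 with an estimated correlation). Among them were the replication genes Mcm2 (1.51) and Mcm3 (2.68) and the cell cycle inhibitor Cdkn1a (2.10). Cytosolic ribosomal protein genes, a list included as a measure of RNA quality, rose by a median of 0.64 (3 of 31, 18 adjusted over the list alone, camera adjusted p = 1.22e-09, and adjusted p = 0.386 with an estimated correlation). Model 3 lay at 1.23 above the sham mean against 0.52 and 0.19 in model 1 and 4. NRF2 targets and antioxidant enzymes did not pass as a list (6 of 28 rose and 1 fell, 9 adjusted over the list alone, median 0.36, camera adjusted p = 0.128). Without model 1 or model 4 the list passed (camera adjusted p = 0.0225 and 0.00796).

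Several lists of blood-borne and vascular cell markers were higher, most of all in model 3, while erythrocyte genes did not pass. Neutrophil genes (2 of 17 rose, 1 fell, 10 adjusted over the list alone) had a median of 2.58, or 2.13 with 4 members at their bound (camera adjusted p = 3.62e-05, and adjusted p = 0.301 with an estimated correlation). Model 3 lay at 4.62 above the sham mean and model 1 and 4 at 2.44 and 1.90. The chemokine receptor Cxcr2 was at 0 in sham and at 278.4 ± 327.9 normalized reads in model (SD, n = 3; at least 79.1-fold higher by the mean), and Mmp9, a matrix protease, had a log2 fold change of 4.44 ± 0.65 (SE). Endothelial and blood-brain barrier genes (6 of 23 rose, 13 adjusted over the list alone, median 1.34, camera adjusted p = 0.000746, and adjusted p = 0.418 with an estimated correlation) included the vascular growth factor receptor Kdr (2.49 ± 0.40 SE) and Esm1 (8.49 ± 1.40 SE, or 10.77 with a pseudocount of 0.1). The endothelial list stood at 2.56 above the sham mean in model 3 and at 0.73 and 0.75 in model 1 and 4. Interferon-stimulated genes (2 of 26 rose, 9 adjusted over the list alone, median 1.54, camera adjusted p = 7.12e-06, and adjusted p = 0.386 with an estimated correlation) stood at 2.6 above the sham mean in model 3 and at 0.30 and 1.2 in model 1 and 4. Lymphocyte genes (1 of 17, Cd8a; 1 adjusted over the list alone; median 1.75, or 1.15 with 3 members at their bound; camera adjusted p = 0.0173, and adjusted p = 0.418 with an estimated correlation) lost their list call without model 3, at a median of 0.17 (camera adjusted p = 0.336). So did pericyte and fibroblast genes (0 of 19, 3 adjusted over the list alone, median 1.09, camera adjusted p = 0.00638, and adjusted p = 0.519 with an estimated correlation), at a median of 0.38 (camera adjusted p = 0.191).

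Microglia and macrophage markers split. Of 26 measured, 6 rose and 3 fell over all genes and 17 passed when adjusted over the list alone, with a median of 0.74 (camera adjusted p = 0.00658, and adjusted p = 0.430 with an estimated correlation). Without model 3 the median was 0.15 (camera adjusted p = 0.0539). Msr1, Lgals3 (4.89 ± 0.59 SE), Gpnmb (3.34 ± 0.55 SE) and the complement gene C1qc (1.90 ± 0.29 SE) rose. The homeostatic microglial genes P2ry12 (-2.07 ± 0.44 SE), Tmem119 (-1.62 ± 0.38 SE) and Gpr34 (-1.82 ± 0.37 SE), chosen after their values were seen, fell, with limma adjusted p of 0.0371, 0.0479 and 0.0319. Their calls were kept in 2, 1 and 3 of the 9 fits without 1 library. Aif1, another microglial marker, did not pass (0.39 ± 0.35 SE; limma adjusted p = 0.542). Astrocyte identity genes were lower as a list (2 of 20 rose, 3 fell, 8 adjusted over the list alone, median -0.59, camera adjusted p = 0.0161, and adjusted p = 0.430 with an estimated correlation). Gfap and Sox9 (1.19) rose, while the growth factor receptor Fgfr3 (-1.09) and the transporter Slc7a10 (-1.94) fell. That list call was lost without sham 5 (camera adjusted p = 0.0793) and without model 1 (camera adjusted p = 0.139).

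Neuronal genes were lower, nearly all by less than a single gene could show. The list calls came from camera alone, since fry called 0 lists as lower between sham and model. For the lists that camera called lower, fry adjusted p ran from 0.0852 (ion channels and receptors) to 0.384 (striatal genes). All 25 pan-neuronal genes had a lower mean in model, with a median of -0.79, and 0 passed over all genes or adjusted over the list alone (camera adjusted p = 2.35e-06, and adjusted p = 0.386 with an estimated correlation). Cortical glutamatergic genes were negative in 21 of 21 with a median of -0.99 and 0 passed by either count (camera adjusted p = 7.26e-05, and adjusted p = 0.317 with an estimated correlation). Their mean lay at -1.89 from the sham mean in model 3 and at -0.85 and -0.31 in model 1 and 4. Ion channels and neurotransmitter receptors had a median of -1.16 (2 of 31 fell, 2 adjusted over the list alone, camera adjusted p = 1.49e-06, and adjusted p = 0.301 with an estimated correlation). Their mean lay at -1.78 in model 3 and at -0.75 and -0.45 in model 1 and 4. The channel genes Hcn2 (-1.21 ± 0.23 SE) and Scn1a (-1.59 ± 0.34 SE) fell. Oligodendrocyte and myelin genes had a median of -0.87 (2 of 23 fell, 9 adjusted over the list alone, camera adjusted p = 1.32e-05, and adjusted p = 0.400 with an estimated correlation). Gpr17 (-1.98) and Opalin (-1.69) fell, while model 3 lay at -0.03 against -1.54 and -0.92 in model 1 and 4. Striatal genes had a median of -0.80 (0 of 18 by either count, camera adjusted p = 0.0134, and adjusted p = 0.520 with an estimated correlation). Sham 5 lay at -1.41 and sham 1 and 3 at 0.60 and 0.81, and the list call was lost without sham 1, sham 3 or model 4 (camera adjusted p = 0.0803, 0.216 and 0.181). Interneuron genes did not pass as a list (median -0.23; 1 of 19 adjusted over the list alone; camera adjusted p = 0.173, or 0.0317 without model 1). Nor did choroid plexus and ependyma (-0.71, 0 of 19, camera adjusted p = 0.582), erythrocyte genes (0.83, 0 of 10, camera adjusted p = 0.518). Mitochondrially encoded transcripts (-0.16, 0 of 13, camera adjusted p = 0.263, or 0.0138 without model 3) and markers of thalamus, hypothalamus, hippocampus and cerebellum (0.12; 1 of 20, Dsp, by either count; camera adjusted p = 0.867) did not pass.

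**Figure D3:**
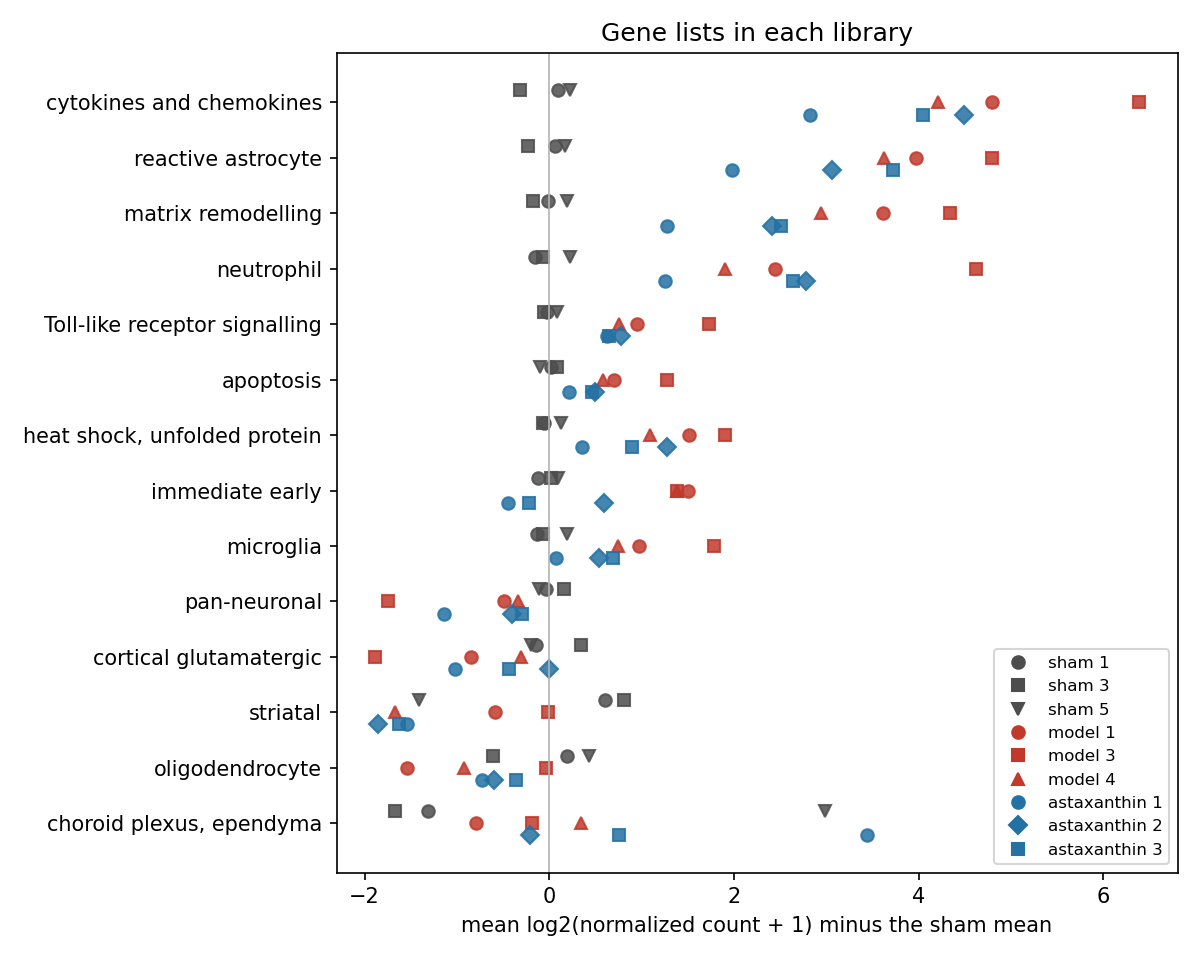
Mean log2(normalized count + 1) of 14 gene lists in each library minus the mean of the sham libraries (log2 units), with colour for the group and marker shape for the library number. Immediate early genes lay between 1.38 and 1.5 in the model libraries and between -0.45 and 0.59 in the astaxanthin libraries, and model 3 was farthest from sham for cytokines, neutrophil and pan-neuronal genes.

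The comparison of astaxanthin with model asked what the treatment changed after occlusion. No single gene passed in limma (0 of 17770, smallest adjusted p = 0.125), and 1579 genes had an unadjusted p under the threshold of 0.05. The groups did not overlap in 12.97% of genes against 10% on average by chance, a difference that was not tested. As a list, immediate early genes were lower in astaxanthin. All 30 had negative log2 fold changes with a median of -1.45, 14 passed when adjusted over the list alone (camera adjusted p = 1.12e-18, and adjusted p = 0.166 with an estimated correlation; fry adjusted p = 0.0347). Their mean lay at 1.5, 1.38 and 1.38 above the sham mean in model 1, 3 and 4 and at -0.45, 0.59 and -0.22 in astaxanthin 1, 2 and 3. Egr2 (chromosome 20, 21051277 to 21055562), an activity-dependent transcription factor, stood at 2202 ± 208 normalized reads in sham, 2520.1 ± 914 in model and 431 ± 135 in astaxanthin (SD, n = 3; log2 fold change -2.52 ± 0.34 SE, limma adjusted p = 0.468). Fos (-1.98 ± 0.39 SE), Dusp6 (-1.51 ± 0.33 SE) and Arc (-2.04 ± 0.45 SE) each had a limma adjusted p of 0.548. The list was lower in each of the 9 fits without 1 library, with medians from -1.71 to -1.03, and without astaxanthin 1 and model 3 together (-1.14, camera adjusted p = 9.85e-18). The fry call was lost in 8 of those 9 fits (fry adjusted p from 0.0754 to 0.148) and kept only without astaxanthin 2 (0.000346).

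Other tools differed on single genes. DESeq2 on the recovered reads called 204 genes, 59 higher and 145 lower in astaxanthin, while edgeR called 0 and limma without model 4 called 3, which were Ltbp1 (-3.02), Hapln4 (2.49) and Thbs1 (-3.35). The genes with the smallest p in limma, none past the threshold, were Mei1 (1.98), Slc12a1 (at 0 in model and at least 5.67-fold higher in astaxanthin), Kcnv2 (at 0 in model, at least 4.30-fold higher) and Coro2b (1.34) on the higher side. On the lower side they were Slc30a4, Egr2, Itga6 (-0.86) and Dusp27 (at 0 in astaxanthin, at least 5.57-fold lower). Slc30a4 (chromosome 3, 109753273 to 109775306), a zinc transporter, had the smallest p of all. It stood at 6066 ± 1166 normalized reads in sham, 7419 ± 1772 in model and 1673 ± 214 in astaxanthin (SD, n = 3; log2 fold change -2.13 ± 0.22 SE, limma adjusted p = 0.125; DESeq2 adjusted p = 3.29e-13). DESeq2 also called Egr2 (-2.55, adjusted p = 1.85e-08) and Fos (-1.88, adjusted p = 0.00605).

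Toll-like receptor signalling genes were lower in astaxanthin as a list, by less than between model and sham. Of 41, 30 had a negative and 11 a positive log2 fold change, the median was -0.38 and 2 passed when adjusted over the list alone (camera adjusted p = 0.00237, and adjusted p = 0.518 with an estimated correlation). The call rested on model 3: without it the median was -0.04 (camera adjusted p = 0.3). Tlr2 (-1.16 ± 0.51 SE), Tlr4 (-1.30 ± 0.54 SE), Myd88 (-1.03 ± 0.37 SE), Cd14 (-1.91 ± 0.61 SE), Nfkb1 (-0.20 ± 0.26 SE) and Rela (-0.38 ± 0.30 SE) did not pass, with limma adjusted p from 0.548 to 0.799. Apoptosis genes were lower as a list (30 of 40 negative, median -0.39, 0 adjusted over the list alone, camera adjusted p = 0.000182, and adjusted p = 0.456 with an estimated correlation). Without model 3 the median was -0.28 (camera adjusted p = 0.0250), and without astaxanthin 1 and model 3 together the call was lost (-0.11, camera adjusted p = 0.120). Bax (-0.35 ± 0.23 SE) and Bcl2 (-0.43 ± 0.26 SE) had limma adjusted p of 0.620 and 0.597.

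Inflammatory, matrix and stress lists that had risen between sham and model were lower in astaxanthin. Cytokines and chemokines were negative in 33 of 36 (median -1.37, 1 adjusted over the list alone), and matrix remodelling genes in 26 of 27 (-1.39, or -1.28 with 1 member at its bound; 3 adjusted over the list alone). Reactive astrocyte markers were negative in 22 of 24 (-1.29), microglia and macrophage markers in 25 of 26 (-0.74), heat shock genes in 25 of 25 (-0.51) and inflammasome and cell death genes in 21 of 24 (-0.72, 3 adjusted over the list alone). Camera gave adjusted p between 1.75e-12 and 2.34e-05 for these 6 lists, and each had an adjusted p = 0.456 with an estimated correlation. The size of these falls depended on single libraries. Without model 3 the medians of cytokines, microglia and inflammasome genes were -0.59, -0.47 and -0.26, and without astaxanthin 1 those of matrix, reactive astrocyte and heat shock genes were -0.82, -0.76 and -0.29. Without both libraries together the cytokine call was lost (-0.24, camera adjusted p = 0.138), and the medians of matrix, reactive astrocyte, microglia, heat shock and inflammasome genes were -0.39, -0.31, -0.29, -0.16 and -0.03. Il1b (-1.80 ± 0.81 SE), Il6 (-1.61 ± 1.16 SE), Tnf (-0.66 ± 0.82 SE), Hmox1 (-1.81 ± 0.70 SE), Gfap (-0.45 ± 0.62 SE) and Aif1 (-0.79 ± 0.35 SE) did not pass in limma. Complement genes (19 of 21 negative, median -0.99, 1 adjusted over the list alone), NF-kappaB feedback genes (19 of 21, -0.82), ribosomal protein genes (30 of 31, -0.48) and cell cycle genes (16 of 24, -0.31) were lower too. Their camera adjusted p were 1.70e-05, 6.76e-05, 4.38e-11 and 0.0135, each with an adjusted p = 0.459 with an estimated correlation. Without model 3 the medians of the first 3 were -0.42, -0.31 and -0.24. The NF-kappaB feedback call was lost without astaxanthin 1 and model 3 together (0.02, camera adjusted p = 0.628), and the cell cycle call was lost without model 1 (camera adjusted p = 0.0638) and without astaxanthin 2 (camera adjusted p = 0.106).

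Several list calls of this comparison rested on model 3 or astaxanthin 1, the libraries with the highest neutrophil or the highest cerebellar and choroid plexus genes. Interferon-stimulated genes (23 of 26 negative, median -0.73), endothelial genes (19 of 23, -0.86), ion channels and receptors (20 of 31 positive, 0.45), cortical glutamatergic genes (14 of 21 positive, 0.49, with 2 adjusted over the list alone) and hypoxia and glycolysis genes (19 of 25 negative, -0.30) passed as lists. Their camera adjusted p were 9.80e-05, 0.00181, 0.00269, 0.00471 and 0.00757, each with an adjusted p = 0.518 with an estimated correlation. Without model 3 the medians of the first 4 were -0.24, -0.12, 0.04 and 0.05 (camera adjusted p = 0.202, 0.570, 0.696 and 0.263). The glutamatergic call was also lost without astaxanthin 2 (0.43, camera adjusted p = 0.195). It was kept without astaxanthin 1 (0.80, camera adjusted p = 1.36e-05) and without astaxanthin 1 and model 3 together (0.32, camera adjusted p = 0.00497). The hypoxia call was lost without model 4 or astaxanthin 1 (camera adjusted p = 0.132 and 0.215). Striatal genes were negative in 18 of 18 (median -0.58, camera adjusted p = 0.00231, and adjusted p = 0.541 with an estimated correlation), or -0.36 without model 3 (camera adjusted p = 0.1). NRF2 targets (-0.33, 1 adjusted over the list alone), pericyte and fibroblast genes (-0.30) and choroid plexus and ependymal genes (1.38) passed with camera adjusted p of 0.00226, 0.0135 and 0.0138, each with an adjusted p = 0.549 with an estimated correlation. Without model 3, NRF2 targets turned to 0.05 and pericyte and fibroblast genes to 0.16, and without astaxanthin 1 the choroid plexus genes stood at 0.24 (camera adjusted p = 0.885, 0.722 and 0.575). The pericyte call was also lost without astaxanthin 2 or 3, where the medians were larger (-0.43 and -0.50, camera adjusted p = 0.106 and 0.0691).

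Pan-neuronal genes (18 of 25 positive, median 0.35) and oligodendrocyte genes (17 of 23 positive, 0.39) passed as higher, with camera adjusted p of 0.0217 and 0.0300, each with an adjusted p = 0.580 with an estimated correlation. Both calls depended on single libraries. Pan-neuronal genes turned to -0.18 without model 3 and lost the call without astaxanthin 2 or 3 (0.18 and 0.14, camera adjusted p = 0.150 and 0.266). Oligodendrocyte genes turned to -0.03 without model 1. Without model 4, astaxanthin 2 or astaxanthin 3 they lost the call at medians of 0.38, 0.37 and 0.32 (camera adjusted p = 0.113, 0.0754 and 0.238). They stood at 0.72 without model 3 (camera adjusted p = 1.07e-06) and at 0.76 without astaxanthin 1 and model 3 together (camera adjusted p = 2.32e-08). Among lists that did not pass were neutrophil genes (median -1.09, camera adjusted p = 0.0567), mitochondrially encoded transcripts (-0.26, camera adjusted p = 0.0567), and lymphocyte genes (-0.72, camera adjusted p = 0.0914). The others were interneuron genes (-0.87, camera adjusted p = 0.137), erythrocyte genes (-0.48, camera adjusted p = 0.198), astrocyte identity genes (median -0.05 but mean 0.09, camera adjusted p = 0.503) and other brain regions (median 0.07, with the test on the lower side; camera adjusted p = 0.942). Leaving out a single library brought the first 6 past the threshold: neutrophil and lymphocyte genes without model 1, model 4 or astaxanthin 2 (camera adjusted p from 0.00839 to 0.0425) and mitochondrial transcripts without sham 3 or model 1 (0.0463 and 0.00228). The same held for interneuron genes without model 3 or astaxanthin 3 (0.0475 and 0.0285), erythrocyte genes without model 4 (0.00844) and astrocyte genes, at 0.32, without model 3 (0.0456). Without astaxanthin 1 and model 3 together, a setting chosen after seeing the data, 12 of the 31 lists passed in place of 24. In every list of this comparison for which no other number is given, 0 genes passed when adjusted over the list alone.

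The comparison of astaxanthin with sham asked what remained different from uninjured brain after treatment. The same inflammatory genes led it. Ccl2 was at 0 in sham and 5626 ± 4898 normalized reads in astaxanthin (SD, n = 3), at least 1600.0-fold higher (limma adjusted p = 0.00128), and Ccl7 was at least 375-fold higher (limma adjusted p = 0.00542). Kng2l1, Kng1, Cxcl2 and Il11, all at 0 in sham, were at least 79.6-fold, 62.3-fold, 43.9-fold and 35.5-fold higher, Msr1 had a log2 fold change of 8.27 ± 0.99 (SE; 10.54 with a pseudocount of 0.1) and the imprinted non-coding RNA H19 one of 6.96 ± 0.74 (SE). The 7 genes that fell were Ankrd63 (-3.28), Gucy1a1 (-2.69), Tmem119 (-2.55), Otof (-2.46), Egr2 (-2.40), Slc30a4 (-1.85) and Snx10 (-1.72), with limma adjusted p from 0.0110 to 0.0444. Of these, Gucy1a1, Otof and Tmem119 had also fallen between sham and model. Egr2 and Slc30a4 had log2 fold changes of 0.12 and 0.28 there, with limma adjusted p of 0.856 and 0.486.

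Altogether 49 genes passed in limma, 42 higher and 7 lower, and the groups did not overlap in 24.3% of genes against 10% by chance. All 42 higher genes were also higher in model against sham, where independent lists would share 1.45, and 3 of the 7 lower genes were shared against 0.0926. Both comparisons use the sham libraries, which adds shared calls without any effect, and groups of 3 could not be split to remove this. The count was 1 without sham 1, 5 without sham 3, 12 without sham 5, 12 without model 1, 111 without model 3, 17 without model 4, 149 without astaxanthin 1, 7 without astaxanthin 2 and 2 without astaxanthin 3. DESeq2 called 781 genes and edgeR 0, with 2192 genes at an unadjusted p under 0.05 in limma, and 713 passed in limma without astaxanthin 1 and model 3 together, a setting chosen after seeing the data. Only Ccl2 among the named genes kept its call in each of the 9 fits without 1 library.

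Toll-like receptor signalling genes stayed above sham as a list (2 of 41 rose, Cd14 at 4.60 ± 0.61 SE and Tlr1 at 2.95 ± 0.42 SE; 6 adjusted over the list alone; median 0.35; camera adjusted p = 0.000399, and adjusted p = 0.519 with an estimated correlation). Tlr2 (0.29), Tlr4 (0.19), Myd88 (1.53), Nfkb1 (0.74) and Rela (0.76) did not pass, with limma adjusted p from 0.174 to 0.917. Of these, DESeq2 called Myd88 alone (1.65, DESeq2 adjusted p = 0.00206). Apoptosis genes stood at a median of 0.39 (0 of 40 over all genes, 2 adjusted over the list alone, camera adjusted p = 0.0318, and adjusted p = 0.534 with an estimated correlation). The call was lost without sham 5, astaxanthin 2 or astaxanthin 3 (camera adjusted p = 0.117, 0.0941 and 0.131). Bax (0.05 ± 0.23 SE) and Bcl2 (-0.61 ± 0.26 SE) did not pass, with limma adjusted p of 0.949 and 0.387.

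Cytokines (7 of 36 rose, 20 adjusted over the list alone, median 3.36, or 2.73 with members at their bound) and reactive astrocyte markers (4 of 24, 22 adjusted over the list alone, median 2.77) remained the most raised lists. Their camera adjusted p were 2.95e-19 and 9.44e-18, with an adjusted p = 0.333 with an estimated correlation for both. Il1b and Tnf, at 0 in sham, were at least 35.0-fold and 23.5-fold higher. In limma, Il6 (6.57 ± 1.16 SE), Hmox1 (4.14 ± 0.70 SE), Gfap (2.35 ± 0.62 SE) and Aif1 (-0.40 ± 0.35 SE) did not pass. DESeq2 called Il6, Hmox1 and Gfap higher (DESeq2 adjusted p = 0.000184, 3.11e-08 and 0.00172), but not Aif1 (0.674). Matrix remodelling genes rose (4 of 27, 13 adjusted over the list alone, median 1.96, or 1.76 with members at their bound; camera adjusted p = 1.40e-13, and adjusted p = 0.401 with an estimated correlation). Complement (median 0.84, 1 of 21 and 3 adjusted over the list alone), neutrophil (2.49, or 2.42 with members at their bound; 1 of 17 and 4), NF-kappaB feedback (0.49, 1 of 21 and 4), heat shock (0.21, 1 of 25 and 4), inflammasome and cell death (0.27, 1 of 24 and 4), cell cycle (0.41, 0 of 24 and 1) and hypoxia genes (0.16, 1 of 25 and 4) rose as lists. Their camera adjusted p lay between 0.000103 and 0.0141, each with an adjusted p = 0.519 with an estimated correlation. The calls of heat shock and hypoxia genes were lost without astaxanthin 2 (camera adjusted p = 0.0922 and 0.258), and that of cell cycle genes without astaxanthin 1 and model 3 together (0.34, camera adjusted p = 0.0591). Endothelial genes (0.66, 0 of 23 and 1) and interferon-stimulated genes (0.64, 0 of 26 and 1) rose with camera adjusted p of 0.0277 and 0.0233, each with an adjusted p = 0.681 with an estimated correlation, and lost the call without astaxanthin 2 (0.0926) and without astaxanthin 3 (0.290). Ribosomal protein genes (0.17, 0 of 31 by either count; camera adjusted p = 0.0277, and adjusted p = 0.774 with an estimated correlation) lost it without sham 1, sham 3 or astaxanthin 3 (0.0614, 0.0501 and 0.180).

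Neural lists were below sham by camera, while fry called 0 lists as lower in this comparison. Striatal genes had the lowest median, -1.44 (0 of 18 over all genes, 4 adjusted over the list alone, camera adjusted p = 2.59e-08, and adjusted p = 0.519 with an estimated correlation). Their means lay at -1.54, -1.86 and -1.63 in astaxanthin 1, 2 and 3, close to -1.41 in sham 5. Pan-neuronal (-0.48), oligodendrocyte (-0.51), interneuron (-1.0), ion channel and receptor (-0.27) and astrocyte identity genes (-0.49, 2 of 20 adjusted over the list alone) were lower with camera adjusted p from 0.000103 to 0.0123, each with an adjusted p = 0.519 with an estimated correlation. In these lists 0 genes passed over all genes. Interneuron genes lay at -1.42, -0.67 and -0.20 in astaxanthin 1, 2 and 3, and lost the call without astaxanthin 1 and model 3 together (-0.62, camera adjusted p = 0.0529). The astrocyte call was lost without sham 5 or astaxanthin 3 (camera adjusted p = 0.116 and 0.0518). Cortical glutamatergic genes (-0.47, camera adjusted p = 0.0277, and adjusted p = 0.575 with an estimated correlation) lost the call without sham 3, astaxanthin 1 or astaxanthin 3 (0.145, 0.0851 and 0.0808). Mitochondrially encoded transcripts were lower (-0.40, camera adjusted p = 0.00253, and adjusted p = 0.520 with an estimated correlation). Immediate early genes did not pass (median -0.15, camera adjusted p = 0.441; 13 of 30 adjusted over the list alone, 6 of them higher), or stood at -0.39 without astaxanthin 2 (camera adjusted p = 0.0120). Microglial genes did not pass (median 0.08 and mean 0.43 with the test on the lower side, camera adjusted p = 0.654; 13 of 26 adjusted over the list alone, 5 of them higher). NRF2 targets did not pass either (median -0.05 and mean 0.30, 2 of 28 adjusted over the list alone, camera adjusted p = 0.654). Also short of the threshold were lymphocyte (1.09, 1 of 17 adjusted over the list alone, camera adjusted p = 0.157, or 0.0386 without astaxanthin 1) and pericyte and fibroblast (0.42, camera adjusted p = 0.181, or 0.0424 without model 3) genes. Choroid plexus (0.91, camera adjusted p = 0.126, or 1.69e-05 without sham 5 and 0.0121 without astaxanthin 2), erythrocyte (median 0.18 with the test on the lower side, camera adjusted p = 0.747) and other region genes (0.03, camera adjusted p = 0.913) did not pass. In the lists of this paragraph without such a number, 0 genes passed when adjusted over the list alone.

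The 848 genes that changed between sham and model lay nearer to sham in the astaxanthin libraries. Of the 613 higher genes, 591 had an astaxanthin mean between sham and model, 16 at or beyond model and 6 at or below sham. Of the 235 lower genes, 212 lay between. The median position was 58% of the change for higher genes and 58.7% for lower genes. The median return toward sham over all 848 was 41.81%. Simulations without a treatment effect kept the shrunken difference of model from sham and gave astaxanthin the model mean. They had a median return of 9.504% with pooled noise, with 2 of 100 as high. With noise by group, which still pooled model and astaxanthin, it was 14.37%, ranging from -31.38% to 79.04%, with 8 of 100 as high. By library the higher genes stood at 40%, 68.9% and 67.4% in astaxanthin 1, 2 and 3 and at 98.3%, 118% and 83.9% in model 1, 3 and 4. The log2 fold change of astaxanthin against model was opposite to that of model against sham in 811 of the 848 genes (95.64%), with 4 at 0 in both groups. Without a treatment effect the simulated median was 67.69% with pooled noise, with a range of 9.788% to 99.76%. There 3 of 100 reached as high. With noise by group the median was 77.12% and the range 15.09% to 98%, and 5 of 100 did. No gene passed between astaxanthin and model in limma or edgeR, so none was called in opposite directions there (0 and 0). Among the genes that DESeq2 called 152 were, and among those of limma without model 4, 3. Across all tested genes, which are not independent replicates, the fold changes of the pair of comparisons had a Pearson correlation of -0.589. Simulations of unchanged groups had a mean of -0.439, since the comparisons share the model libraries. The simulations ranged from -0.977 to 0.699, with 42 of 100 as low, or 45 with noise by group. Their covariance was -0.582 against a simulated mean of -0.255, a difference of -0.327, and 6 of 100 simulations went as low; with noise by group the difference was -0.267, and 16 of 100 did. For model and astaxanthin each against sham, the correlation was 0.733 against a simulated mean of 0.435 with a range of -0.742 to 0.947 and 23 of 100 as high, or 24 with noise by group. The covariance was 0.860 against 0.268, with 5 of 100 as high, or 2 with noise by group.

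**Figure D4:**
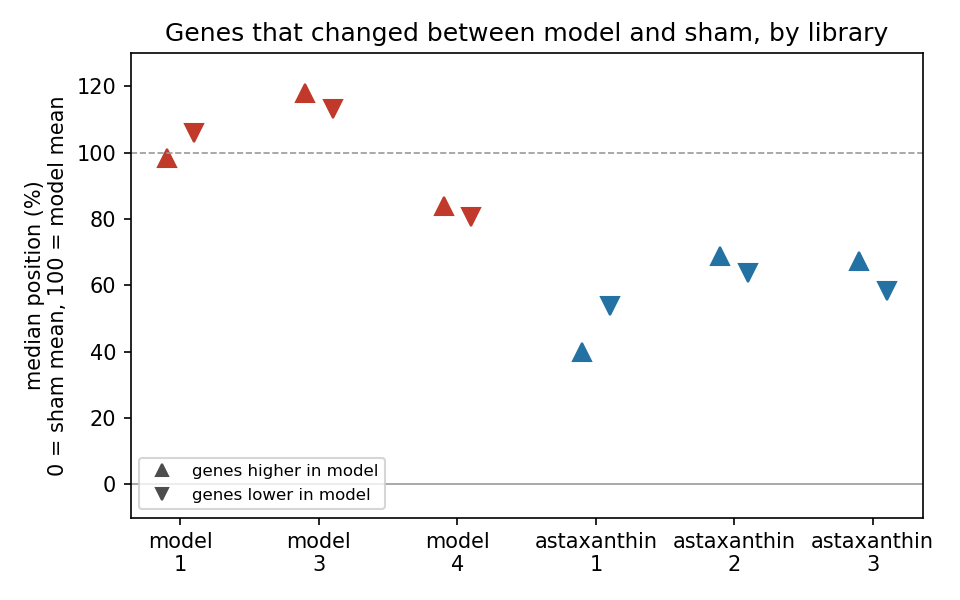
Median position (percent, 0 at the sham mean and 100 at the model mean) of the genes that changed between sham and model, for each model and astaxanthin library, with upward triangles for genes higher and downward triangles for genes lower in model. The astaxanthin libraries lay between 40 and 68.9 and the model libraries between 80.5 and 118.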

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

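The tests of the transcript counts and of read assignment were chosen after the result was seen. The transcript table, which no comparison above used, was flagged because transcripts passed the threshold in it: tested like the genes (32824 transcripts, limma adjusted p under 0.05), 226 transcripts differed between model and sham, 17 between astaxanthin and model and 67 between astaxanthin and sham. Of these, 59 of the 226 and 46 of the 67 came from genes that did not pass themselves; between astaxanthin and model no gene passed. Of the 17, 11 were at 0 in all libraries of a group. A transcript of Nell2 (ENSRNOT00000099152, chromosome 7, 126343090 to 126662028) had 0 reads in sham and model and 10280 ± 4091 normalized reads in astaxanthin (SD, n = 3; limma adjusted p = 0.000354). A transcript of Tubb6 (ENSRNOT00000107745) was seen in model alone, at 1963 ± 877 normalized reads (SD, n = 3). For Dync1li2, ENSRNOT00000097230 fell from 5522 ± 1009 in sham to 213.9 ± 48.6 in model and stood at 5571 ± 895 in astaxanthin (SD, n = 3; log2 fold changes -4.69 and 4.71). The main transcript of Slc30a4 was lower in astaxanthin than in model (-2.57, limma adjusted p = 0.0161), and so was a transcript of Dusp6, ENSRNOT00000111909 (-3.84, limma adjusted p = 0.0356).

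Other splits of the same 6 libraries show how far such counts go without the real groups, though 10 splits are too few for a share under 0.05. For model against sham, 1 split of 10, the real one, had as many transcripts (226, next highest 23), and for astaxanthin against sham 1 of 10 did (67, next highest 29). For astaxanthin against model, 5 of 10 splits had at least 17, and the highest had 33, so those 17 transcripts cannot be told apart from what other groupings of the libraries give.

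Some transcripts were all or none: at 0 on 1 side and at 100 or more normalized reads in every library of the other. Among the changed ones these were 23 of 226, 9 of 17 and 22 of 67. Of Hadhb (chromosome 6, 26153578 to 26184869), ENSRNOT00000085613 had 4318 ± 1206 normalized reads in sham and 0 elsewhere, while ENSRNOT00000014637 had 0 in sham, 5792 ± 1153 in model and 4589 ± 808 in astaxanthin (SD, n = 3), and their annotated lengths were 2169 and 2143 bases. Reads assigned to 1 of several overlapping transcripts differently in each library may explain such pairs. Over all transcripts, changed or not, there were 20 all-or-none ones for astaxanthin against model in the real split and up to 29 in other splits, as that explanation needs. For model against sham there were 56 against at most 32, and read assignment cannot be told apart there from a change of isoform, since 10 splits are too few. Isoform choice after occlusion or treatment stays an untested biological explanation.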

How the results depend on the processing

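The alternatives tried only after the data were seen were array weights, the fits without astaxanthin 1 and model 3 together, and the fit of libraries 1 and 3 without a block. The first choice of test for raw counts, edgeR, was also run on the recovered reads only then. Other size factors, the filters of 1 read or 1 CPM and moderation without the robust option kept every count of genes within 1.5 times the values given above. DESeq2 called 2943 genes for model against sham, 204 for astaxanthin against model and 781 for astaxanthin against sham, with 152 called in opposite directions. By edgeR the counts were 761, 0 and 0. All 19 genes named as past the threshold for astaxanthin against sham lost their call in edgeR. The cause of these differences was not tested. Without a filter the counts were 355, 6 and 21, with 4 called in opposite directions, and at an adjusted p under 0.01 they were 72 and 4 for model and astaxanthin against sham. Fitting only the 6 libraries compared left 4 genes for astaxanthin against sham, and a pseudocount of 0.1 gave 75. A replicate block on libraries 1 and 3 left 0 and 0 genes in the comparisons with sham, where the same libraries without a block gave 31 and 1. Equal numbers correlated between -0.123 and 0.067 in their deviations, and unequal numbers between -0.171 and 0.16. This gave no sign that the numbers pair the samples, but so few libraries cannot exclude it. Array weights, which were lowest for model 3 (0.216) and astaxanthin 1 (0.235), gave 3287, 2 and 1294 genes and 14 lists for astaxanthin against model. Without those libraries together the counts were 2710, 0 and 713 genes and 12 lists. Camera with an estimated correlation called 0 lists for model against sham, 0 for astaxanthin against model and 0 for astaxanthin against sham, and fry 13, 1 and 2. The fry calls in the comparisons with sham were all higher, and the 1 between astaxanthin and model was lower.

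Leaving out 1 library at a time gave 72 to 1608 genes for model against sham, 0 to 3 for astaxanthin against model, 1 to 149 for astaxanthin against sham and 0 to 3 called in opposite directions. Between astaxanthin and model, some list medians turned sign. NRF2 targets ranged from -0.62 (without model 4) to 0.05 (without model 3), and stood at 0.07 without astaxanthin 1 and model 3 together. Pan-neuronal genes ranged from -0.18 (without model 3) to 0.63 (without model 4), oligodendrocyte genes from -0.03 (without model 1) to 0.72 (without model 3), and pericyte and fibroblast genes from -1.04 (without model 1) to 0.16 (without model 3). Fewer libraries enter these fits, and the cause was not tested. The correlation of fold changes ranged from -0.692 to -0.509 over the settings in which it was computed. With 3 libraries per group, changes near 2-fold were mostly below what the test could find, and genes at 0 in a group have fold changes bounded by depth.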

Other observations

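Of the tests in this part, those of the choice of genes on the model libraries, of other tissue in astaxanthin 1 and of all explanations for the immediate early genes were chosen after the result was seen; those of less injured tissue for the genes nearer to sham and of other splits were written before. Among microglial genes, chosen after their values were seen, P2ry12 stood at 987 ± 48.6 normalized reads in sham, 237 ± 45.3 in model and 280.4 ± 149 in astaxanthin, and Tmem119 at 1501 ± 293, 490 ± 117 and 274 ± 144 (SD, n = 3). The log2 fold change of Tmem119 between astaxanthin and model was -0.93, that of P2ry12 0.08, that of Msr1 -0.94 and that of Gpnmb -0.71. None of them passed, and differences between these genes were not tested.

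Other splits of the same 6 libraries, 10 per comparison and too few for a share under 0.05, gave as many genes as the real split in 1 of 10 for model against sham (848, next highest 1) and in 1 of 10 for astaxanthin against sham (49, next highest 2), and in 10 of 10 for astaxanthin against model, where the count was 0. Counts of lists as large arose in 5 of 10 splits for model against sham (25, highest other 27), in 3 of 10 for astaxanthin against model (24, highest other 25) and in 1 of 10 for astaxanthin against sham (23, highest other 14). List calls for the first 2 of these cannot be told apart by their number from what other groupings of the libraries give.

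The genes changed between sham and model lay nearer to sham in all 3 astaxanthin libraries. Choosing the genes on the model libraries was argued against as the whole cause, though only by 3 libraries per group. Each model library was left out, and the 848 genes with the smallest p in the fit of the other 8 libraries were taken. The left-out library lay higher than each astaxanthin library in 9 of 9 pairs, for example model 4 at 62.4% against 36.0%, 51.8% and 50.5%. These pairs share their libraries and are not 9 separate results. Simulations that chose the genes on all model libraries, without a treatment effect, had as high a median return in 2 of 100 with pooled noise. With noise by group 8 of 100 did, so chance is not excluded. Cerebellar and choroid plexus tissue in astaxanthin 1 could not set the positions of astaxanthin 2 and 3. These lay lower in 6 of 6 pairs, which are among the 9 above and add no separate evidence. Less injured tissue in the astaxanthin samples stays open. By the share of the rise kept, 0 lists had a median outside the middle range (quartiles) of all higher genes on the same side in all 3 libraries, but that range of single genes is too wide to show an even response. In astaxanthin 3 alone, endothelial (15.1%) and immediate early genes (19.7%) lay below the range of 23.8% to 59.8% and microglial genes (73.1%) above it. A smaller injury after treatment and a sample with less of the injured tissue cannot be told apart, and shared model libraries add to the pattern.

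Immediate early genes were lower in astaxanthin than in model in every library. Fewer striatal neurons cannot be told apart from other causes: the striatal list fell less, with a median of -0.58 and a mean of -0.91 against a mean of -1.45, but its members had an SD of 0.81. Model 4, with the striatal list at -1.67, kept its immediate early genes at 1.38, and sham 5, at -1.41, had them at 0.10, but single libraries exclude nothing. Less injured tissue stays open: 2 astaxanthin libraries lay below the lowest sham library, which less injury alone does not require, while astaxanthin 2 lay above every sham library. Handling before the tissue was taken cannot be told apart from treatment, since the lowest model library lay 0.79 above the highest astaxanthin library and the labels give no times of day. An effect of astaxanthin on neuronal activity stays open and untested.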
